A study of Mus musculus with 6 samples.

How the data were processed

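MNase-seq was carried out on mouse sperm from the epididymis and vas deferens. In this assay micrococcal nuclease (MNase) digests accessible DNA and leaves DNA that is wrapped in nucleosomes. Sperm chromatin is mostly packed by protamines, so nucleosome-sized fragments mark the sites where histones are still bound. Per the labels' protocols, sperm were first treated with DNase I, then permeabilised, decondensed with DTT and digested in 2 rounds with 5 and 15 units of MNase, and mononucleosome-sized DNA was cut from an agarose gel. Libraries carried unique molecular identifiers, per the labels' protocols. There were 6 libraries, 4 from wild-type animals (WT) and 2 from animals with the K49A substitution in protamine 1 (K49A). The groups and replicate numbers came from the sample titles, which call the mutant libraries MT. The name K49A is in their file names. The series design calls the libraries of each genotype biological replicates of C57BL/6 wild-type or mutant mice. The labels' protocols state the sperm input per genotype and not per library, so how many animals stand behind a library is not given in the sources used here. Permutation p-values measure the spread between these libraries. Fisher p-values are taken across the genes of 1 library and hold no spread between libraries.

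The deposited files are lists of enriched regions (broad peaks), one list per library. Reads were handled with FastQC, BWA, Picard and SAMtools, peaks were called with MACS2, and the genome build was mm10, per the submitters' processing notes. Versions, settings, the use of an input control and the use of the identifiers to remove duplicates are not given in the sources used here. For each peak the authors' files give a fold enrichment over background as a ratio, a −log10 p and a −log10 q. They also give a whole-number score, which in the deposited files was the integer part of 10 times the −log10 q in at least 99.8% of the peaks of each list. Every fold, p and q is the authors' own value for that peak. The lowest −log10 q was between 1.00 and 1.04 in each list, so the lists end at a q of 0.1. That limit corresponded to a lowest −log10 p of 3.32 to 3.75 in WT and of 4.55 and 4.73 in K49A. Peak names are numbered, and between 82 and 88 numbers were absent from each list, which the file names attribute to removal of blacklisted regions.

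No read counts were used, and the total depth of the libraries is unknown. The fold and the p of a peak together fix a background pileup (reads expected over a position) if p is a Poisson tail and 1 is added to both terms of the fold. This was solved for peaks of at most 400 bp with a −log10 p under 100, and the median was taken as a relative measure of depth. It is approximate, because the caller's values are averages over a peak.

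Peaks were placed against the protein-coding genes of a RefSeq gene table for GRCm38.p6, the assembly that mm10 names (21887 genes on chromosomes 1 to 19, X and Y). The table has gene starts and ends but no strand, exons or sequence. The analysis planned before the data were examined called for promoters, CpG islands, repeats and GC content. Promoters were replaced by windows of 1 kb either side of both annotated ends of a gene, so that a peak at a gene end is at the start or at the finish of the gene. The other measures were not analysed here. A peak was at a gene end, or shared with another list, if it overlapped by at least 1 bp, and in a gene body if its midpoint was between the ends of a gene. For a chance level, the peaks of each library were placed at random on their own chromosome 100 times, between the outermost annotated gene or peak. Regions for comparison across libraries were made by merging the 6 lists.

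The library was the unit of replication. Groups were compared with a two-sided exact permutation test over the 15 splits of 6 libraries into 4 and 2. The smallest two-sided p that this test can give with 4 and 2 libraries is 0.133, so it could not reach 0.05. Tests that assume a distribution were not used with so few libraries. A p of 0.133 is stated where the groups did not overlap at all. Numbers, lengths and widths were tested as log2 values and shares as percentages. No test was made per gene or per region. The 16 gene lists were written before the data were examined. For each list and library, members with a peak at a gene end were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 96 tests. Neighbouring genes can share a peak, so these p-values are too small for clustered families. Odds ratios had 0.5 added to each cell.

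Genes named in the text followed a rule set beforehand. It took the 10 genes with the highest mean percentile of their best peak (by −log10 q within its own list) among genes with a peak in all 4 WT and neither K49A library, likewise among genes with a peak in all 6 libraries, and all genes with a peak in both K49A and no WT library. It also took up to 4 members of each list. Some genes that the rule took are not reported here. Prm1 was always looked up, and 3 regions of each class were named in the same way. Genes inside dense stretches of the genome were named after their values were seen.

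Alternatives were a −log10 q of at least 5, lists cut to the 700 strongest peaks (the length of the shortest list), merging within 1 kb, autosomes only, a width of at least 300 bp, coverage by 0.5 of the length, all annotated genes, leaving out each library, and pairing of libraries by the number in the title or by file name. The file names and the titles disagree on the partner of K49A 2, which is WT 4 by file name and WT 2 by title, while both pair K49A 1 with WT 1. A common p level (−log10 p of at least 5, 6, 10 or 20) and windows of 500 and 2000 bp were chosen after seeing the data. The scripts were tested on simulated data. A planted share at gene ends of 42.4% among 20458 peaks modelled on WT 2 was recovered as 42.4%, and a planted overlap of 30% modelled on WT 4 as 30.7%. Known background pileups of 4 and 6.5 were recovered exactly. There p was computed with the same formula that was solved, so this checks the solver and not the measure of depth. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Confidence intervals (95%, exact Clopper-Pearson) cover counting error only.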

Results

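Nucleosome-sized DNA left after MNase digestion was profiled in mouse sperm to compare the places where nucleosomes are found in wild-type sperm and in sperm whose protamine 1 carries K49A, an exchange of a lysine for alanine. Protamine 1 is one of the small basic proteins that replace histones when the sperm nucleus is packed. The data were lists of enriched regions for 4 WT and 2 K49A libraries. The background pileup derived from the lists, a relative measure of depth, was 4.26, 4.94, 5.00 and 5.58 in WT 1 to 4, and 4.19 and 6.55 in K49A 1 and 2. The genotypes did not separate in this measure (exact permutation test, two-sided p = 0.933), and the deepest library by it was K49A 2.

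The first question was how much of the genome was called as enriched in each genotype. Both K49A lists were shorter than every WT list. The WT lists held 20478 ± 6885 peaks (SD, n = 4, range 11313 to 27903) and the K49A lists 859 ± 224 (SD, n = 2, 700 and 1017), a difference of -4.53 ± 0.39 on the log2 scale (SE), or 23.1-fold. WT peaks covered 11.9 ± 4.11 Mb (SD, n = 4) and K49A peaks 0.342 ± 0.0955 Mb (SD, n = 2). The median peak width in K49A was 298 ± 4.95 bp (SD, n = 2) against 467 ± 96.4 bp (SD, n = 4). In all 3 measures every WT library lay above both K49A libraries (exact permutation test, two-sided p = 0.133, the smallest this test can give). In the pairs of libraries whose file names are alike, WT 1 had 16.2-fold more peaks than K49A 1, and WT 4 had 27.4-fold more than K49A 2. The sample titles instead give K49A 2 the number of WT 2, which had 20.1-fold more peaks, and which pairing is right is not known.

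The gap was largest among weaker calls. With a −log10 p of at least 5 in every library the difference was 10.8-fold, at 6 it was 7.57-fold, and at 10 it was 2.25-fold, with no overlap between genotypes at any of these levels. At a −log10 p of at least 20 the WT lists held 135 ± 11.2 peaks (SD, n = 4) and the K49A lists 114 ± 18.4 (SD, n = 2), and the groups overlapped (exact permutation test, two-sided p = 0.267). Covered length and median width also overlapped between genotypes at that level, with log2 differences of -0.31 and -0.03 (exact permutation test, two-sided p = 0.4 and 0.267), and with 700 peaks per list the difference in covered length was -0.69. The size of the difference in peak number therefore depended on the threshold, and the authors' q limit corresponded to a weaker p in WT (lowest −log10 p of 3.32 to 3.75) than in K49A (4.55 and 4.73).

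**Figure D1:**
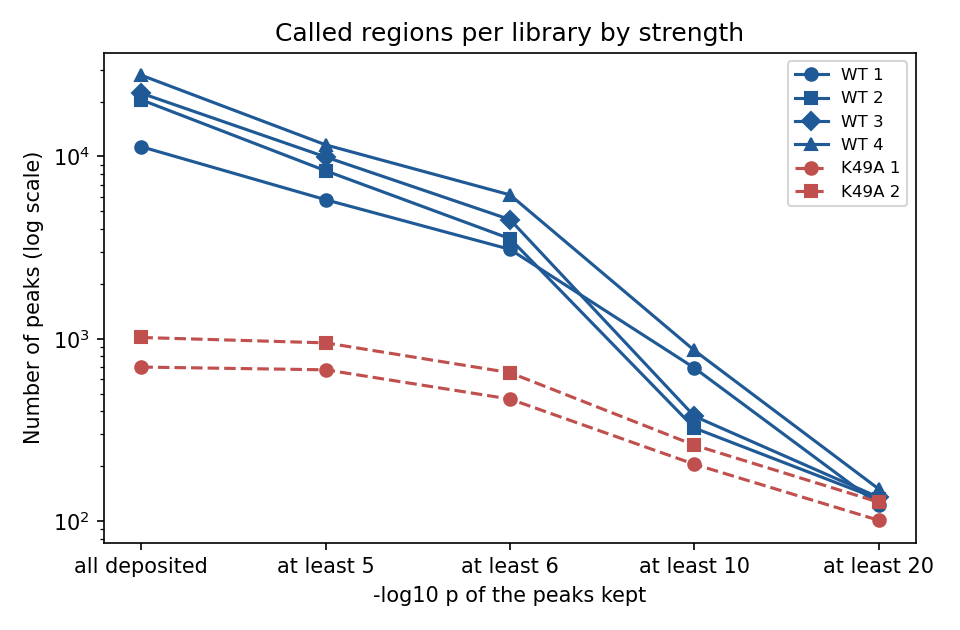
Number of peaks per library (log axis) against the lowest −log10 p of the peaks kept, with WT libraries as solid blue lines and K49A libraries as dashed red lines. All WT libraries lie above both K49A libraries up to a −log10 p of 10, and at 20 they hold 123 to 150 peaks against 101 and 127.

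The enriched regions of wild-type sperm were concentrated at the ends of protein-coding genes, and those of K49A sperm were not to the same degree. In WT, 43.3 ± 5.87% of peaks (SD, n = 4, range 36.7 to 51.0%) lay within 1 kb of a gene end, where random placement gave 3.87 to 4.07%. In K49A the share was 9.83 ± 3.47% (SD, n = 2), with 12.3% (95% interval 9.95 to 14.9%) in K49A 1 and 7.37% (5.84 to 9.16%) in K49A 2, and random placement gave 3.52 and 3.58%. Both K49A shares were above all 100 of their random placements, which reached 5.29 and 4.82%. Midpoints of peaks fell in gene bodies in 63.9 ± 3.03% of cases in WT (SD, n = 4) and in 36.4 ± 1.03% in K49A (SD, n = 2). Random placement gave 40.3 to 40.6% for WT and 39.0 and 39.4% for K49A, so the K49A values were within the random range and the WT values above it.

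Both shares differed without overlap between genotypes (exact permutation test, two-sided p = 0.133, the smallest this test can give). Cutting every list to its 700 strongest peaks left 51.2 ± 7.28% of WT peaks at gene ends (SD, n = 4) and 9.93 ± 3.33% of K49A peaks (SD, n = 2). Within pairs the shares were 51.0 and 12.3% for WT 1 and K49A 1, and beside the 7.37% of K49A 2 the share was 36.7% in WT 4 (alike in file name) and 42.7% in WT 2 (alike in title). At a −log10 p of at least 6 the shares were 61.3 ± 5.02% in WT (SD, n = 4) and 8.28 ± 1.31% in K49A (SD, n = 2), and at 20 they did not separate, with 11.2 ± 1.80% in WT (SD, n = 4) and 11.8 ± 0.0496% in K49A (SD, n = 2; exact permutation test, two-sided p = 0.667).

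**Figure D2:**
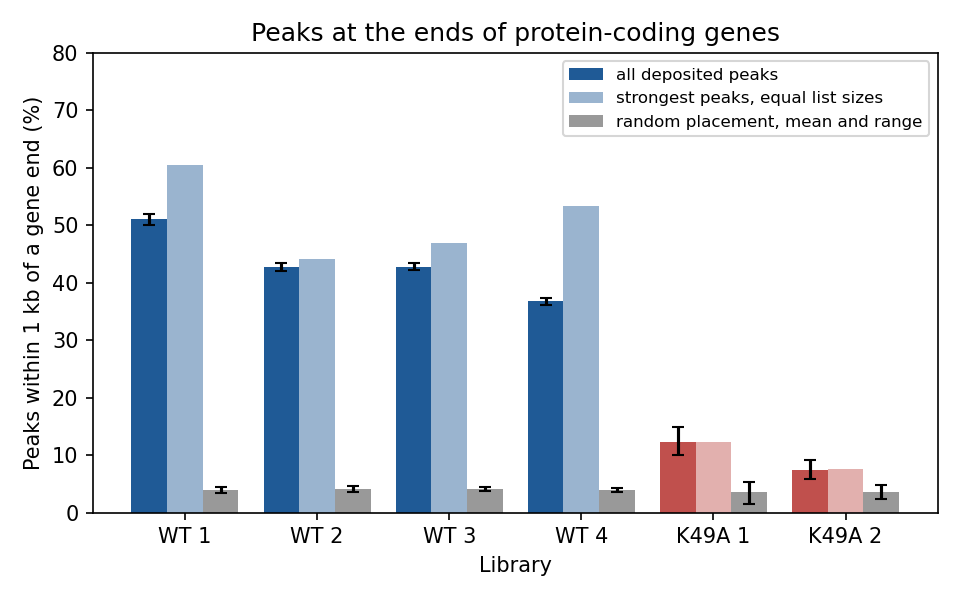
Percent of peaks within 1 kb of an end of a protein-coding gene in each library, for all deposited peaks (dark bars, 95% exact binomial intervals), for the 700 strongest peaks (light bars) and for 100 random placements (grey bars, mean and range). WT libraries (blue) lie between 36.7 and 51.0% for all peaks, and K49A libraries (red) at 12.3 and 7.37%.

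Of 44743 merged regions, 6161 were called in all 4 WT libraries and in neither K49A library. Of these, 72.0% lay at a gene end, and their median width was 1281 bp. Another 257 regions were called in all 6 libraries, of which 9.34% lay at a gene end, and 21 were called in both K49A libraries and in no WT library. The count of WT-only regions follows in part from the lengths of the lists, and with 700 peaks per list 24 regions were called in all 4 WT and neither K49A library and 130 in both K49A and no WT library. It also depended on the WT libraries and on the definition of a call, and was 9485 without WT 1, 1515 when 0.5 of a region had to be covered, 1818 at a −log10 p of at least 5 and 50 at a −log10 q of at least 5.

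At the level of genes, 4849 of 21887 protein-coding genes had a peak at an end in all 4 WT libraries, and 4764 of these (21.8% of all genes) had none in either K49A library. Per library, 6302, 9409, 10135 and 10911 genes had such a peak in WT 1 to 4, and 94 and 73 in K49A 1 and 2. The strongest genes of the WT-only class had moderate enrichment, with mean folds of 4.13 to 5.11. They included Mark1, which encodes a microtubule-affinity regulating kinase (chromosome 1, 184896424 to 184999954), with a fold of 4.96 ± 0.773 (SD, n = 4). Its WT 4 peak spanned 184999354 to 185000036, over the high end of the gene. Grb2, an adaptor of receptor tyrosine kinase signalling (chromosome 11, 115644045 to 115708597), had 5.11 ± 1.26 (SD, n = 4). Slc23a2, a vitamin C transporter (chromosome 2, 132052496 to 132145320), had 4.88 ± 0.568, and Syt7, a calcium-sensing synaptotagmin (chromosome 19, 10388802 to 10453181), 4.61 ± 0.745 (SD, n = 4 each). The others were Yaf2, Cacna1i, Plce1, Ranbp9, and Ptgfrn and Gm52612, which shared the same peak.

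There were 24 genes with a peak in all 6 libraries. The first 10 by rank had mean WT folds of 12.8 to 30.6. They were Pdzd8, Oasl1, Slc22a29, Lars2, Zbtb10, Anp32e, Taco1, Pnck, and the neighbours Cryzl1 and Itsn1 with a shared peak. At Pdzd8, Slc22a29, Anp32e and Pnck the peak had identical borders in all 6 libraries, and at Taco1 in all but WT 2. At Anp32e, which encodes a chaperone of the histone variant H2A.Z (chromosome 3, 95929245 to 95947387), that peak spanned 95929996 to 95930214. The authors' folds at Anp32e were 26.1 ± 3.72 in WT (SD, n = 4) and 13.9 ± 0.242 in K49A (SD, n = 2). At Slc22a29, a solute carrier gene, they were 30.6 ± 2.75 and 14.6 ± 1.34, and at Pnck, a calmodulin-dependent kinase gene, 23.1 ± 0.629 and 10.6 ± 4.67. At Cryzl1 and Itsn1 they were 12.8 ± 4.28 and 12.9 ± 2.36 (SD, n = 4 and 2 throughout). Each fold is relative to its own library's local background, so folds describe a peak within its list and were not compared between genotypes. Only Gm21083 on chromosome 5 and Gm7592 on chromosome 1 had a peak at an end in both K49A libraries and in no WT library. Prm1, the mutated gene (chromosome 16, 10796332 to 10796823), had no peak at either end in any of the 6 libraries.

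Developmental regulators stood out among the gene lists in wild-type sperm. Of 54 developmental signalling genes, 71.3 ± 3.21% had a peak at a gene end in WT (SD, n = 4), against 41.9% of other genes, and the list was past an adjusted p of 0.05 in all 4 WT libraries (Fisher's exact test, Benjamini-Hochberg, largest adjusted p = 0.0037). In all, 25 of its members had a peak in all 4 WT libraries and neither K49A library. Examples were Gdf11, a TGF-beta family ligand, with a fold of 4.49 ± 1.12, and Wnt5b, a Wnt ligand, with 4.25 ± 1.53 (SD, n = 4 each). Bmp7, a bone morphogenetic protein, had a peak in all 6 libraries, and Fgf5 in all 4 WT libraries and in 1 K49A library. Of 129 developmental transcription factors, 61.2 ± 11.1% had a peak in WT (SD, n = 4), again past the threshold in all 4 libraries (Fisher's exact test, largest adjusted p = 0.00036). In all, 44 members were in the class of all 4 WT and no K49A libraries, among them Lhx2 (3.29 ± 0.352) and Six6 (3.14 ± 0.221; fold, SD, n = 4 each), which act in forebrain and eye development. Eomes, a mesoderm regulator, had its best peak at the low end of the gene in all 4 WT libraries. Its peak in 1 K49A library, K49A 2, lay at the high end instead (118487047 to 118487403), with a −log10 q of 1.03.

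Of 39 Hox genes, which pattern the body axis, 50.0 ± 9.48% had a peak in WT (SD, n = 4), and the list passed the threshold in 0 of 4 WT libraries (smallest adjusted p = 0.336, Fisher's exact test). Hoxa13, Hoxb9 and Hoxc8 had peaks in all 4 WT libraries only, and Hoxc10 also in 1 K49A library. Imprinted genes had a peak in 56.6 ± 9.43% of 57 members in WT (SD, n = 4), past the threshold in 2 of 4 libraries, with Inpp5f (fold 4.88 ± 1.19), Impact (4.62 ± 1.03), Peg12 and Herc3 called in all 4. Ribosomal protein genes had 53.0 ± 15.5% of 84 members, past the threshold in 2 libraries. Their named members were Rps20, Rpl7a, Rpl14 and Rps19. Housekeeping genes had 52.5 ± 18.9% of 40 members, past it in 0 libraries, with Ppia, Vps29 and Rab7 called in all 4 WT libraries (SD, n = 4 for each list).

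Germ cell genes did not differ from other genes in a single direction. Both lists had a share of 25% in WT 1, against 28.8% of other genes, while meiotic and early germ cell genes had 59.6% against 46.3% in WT 3. Of 76 spermatid and sperm genes, 40.5 ± 10.5% had a peak in WT (SD, n = 4), with Crem, a transcriptional regulator of spermatids, Ropn1l and Spata6 called in all 4 WT and neither K49A library, and Spata19 also in 1 K49A library. Of 52 meiotic and early germ cell genes the share was 47.6 ± 15.9%, with Sycp1 and Sycp2 of the synaptonemal complex, Asz1 and Kitl called in all 4 WT libraries only. Neither list was past the threshold in any library, and whether they equal other genes was not tested.

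Receptor families and markers of other cell types had few peaks in wild-type sperm. A peak at a gene end was found for 1.29 ± 0.349% of 1106 olfactory receptor genes (SD, n = 4) and for 0.567 to 2.27% of 353 vomeronasal receptor genes, below other genes in all 4 WT libraries (Fisher's exact test, largest adjusted p = 1.1e-148 and 5e-48). Olfr94 and Olfr95 were the olfactory receptor genes called in all 4 WT libraries, and Vmn2r115 was called in 3 WT libraries and in 1 K49A library. The share was 7.93 ± 4.17% of 41 epididymal epithelium genes, again lower in all 4 libraries (largest adjusted p = 0.00022, Fisher's exact test), with Defb42 the only member called in all 4. It was 18.9 ± 4.93% of 37 leukocyte genes, below other genes in all 4 libraries and past the threshold in 3, with Cd3d and C1qb called in all 4 (SD, n = 4 for each). The sex chromosome spermatid list, at 12.5 ± 4.41% of 34 genes, was lower in all 4. Its named members all lie on autosomes, namely Mageb3 and Slx4ip on chromosome 2, Slx4 on chromosome 16 and Slx1b on chromosome 7. Slx4, Slx4ip and Slx1b are DNA repair genes that entered the list through their symbols. They were called in 4, 3 and 3 WT libraries, where the list had 2 to 5 members with a peak, so they raise its share. Pluripotency and early embryo genes (23.3 ± 6.42% of 45) were below other genes in all 4 WT libraries and past the threshold in 3. Klf2, Tead4 and Fgf4 were called in all 4 WT libraries only and Duxf3 in all 6. Canonical histone genes (31.5 ± 11.9% of 65, among them H4c14, H3c6, and H2ac15 and H2bc15 with a shared peak) and clustered protocadherin genes (28.1 ± 15.2% of 57, among them Pcdhac2, Pcdha1 and Pcdhgc3) were each below other genes in all 4 WT libraries and past the threshold in 1 (SD, n = 4).

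In K49A, 10 of the 16 lists had no member with a peak in either library, and no list had more than 3. With 94 and 73 genes called in all in K49A 1 and 2, a low share of members follows for almost any list. Olfactory receptors, with 0 of 1106 members called, were past the threshold in 1 K49A library (Fisher's exact test, adjusted p = 0.0421), and no other list was in either. Relative to other genes, a comparison of the lists between genotypes had little content at these counts, since the odds ratio of an empty list is set by the 0.5 added to each cell. By that measure 15 lists were higher in both K49A than in all 4 WT libraries and 0 were lower, including lists with no K49A member.

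**Figure D3:**
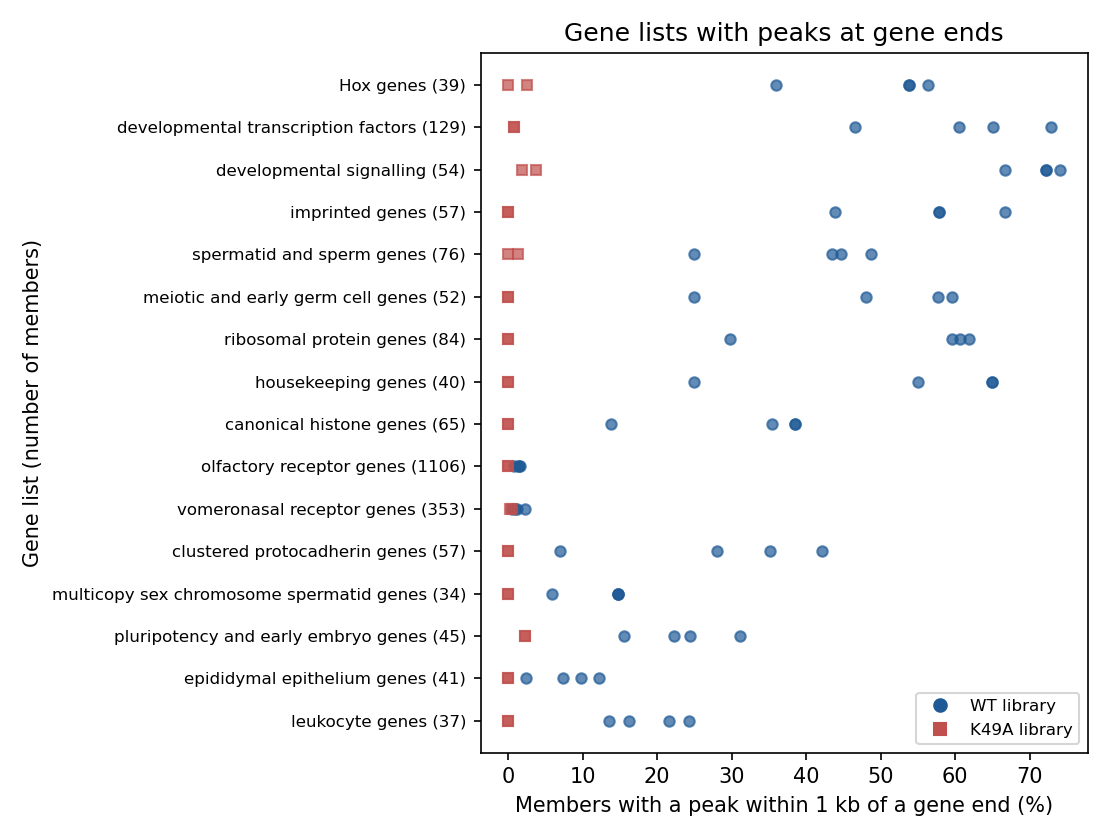
Percent of the members of each gene list with a peak within 1 kb of a gene end, with 1 point per library (blue circles WT, red squares K49A) and the number of members in parentheses. Developmental signalling genes reach 66.7 to 74.1% in WT and at most 3.70% in K49A.

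The K49A lists were partly a subset of the WT lists. A K49A peak overlapped a peak of a given WT library in 55.6 ± 9.58% of cases (SD over 8 ordered pairs), against 0.782% for random placement, whereas 2.46 ± 0.785% of WT peaks overlapped a peak of a given K49A library (SD over 8 ordered pairs). WT libraries overlapped each other in 53.1 ± 15.1% of peaks (SD over 12 ordered pairs). In K49A 1, 79.1% of peaks and in K49A 2, 64.9% of peaks were found in at least 1 WT library. Among K49A peaks with a −log10 p of at least 20, 98.0 and 96.9% were called in all 4 WT libraries. With lists of 700 peaks each, overlap was 42.1 ± 5.07% between WT libraries, 51.9 ± 0.303% between K49A libraries and 30.9 ± 3.49% from K49A to WT (SD over ordered pairs). The excess of overlap within genotypes over that between them was 12.9 percentage points, the largest of all 15 splits (exact permutation test, one-sided p = 0.0667, the smallest possible), and the next split gave 7.35.

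**Figure D4:**
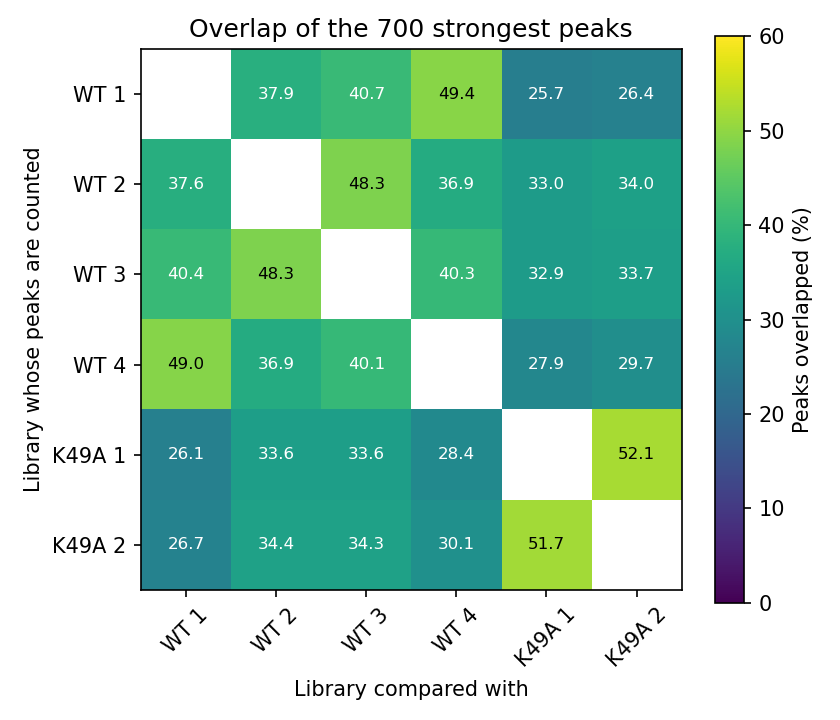
Percent of the 700 strongest peaks of each library (rows) that overlap such a peak of another library (columns) by at least 1 bp, with the colour scale from 0 to 60%. The K49A libraries overlap each other in 51.7 and 52.1%, and overlap between a K49A and a WT library, in either direction, is 25.7 to 34.4%.

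The leading regions called in all 6 libraries were 1 outside genes and 2 in genes. The first was on chromosome X from 143482905 to 143483210, 35156 bp from the nearest annotated gene, Pak3, with folds of 30.8 ± 0.212 in WT (SD, n = 4) and 30.4 ± 0.104 in K49A (SD, n = 2). The next lay in Mdga2 on chromosome 12 (67059095 to 67059885), with 12.7 ± 0.717 and 12.8 ± 0.0372, and at Cldn34d on chromosome X (76598470 to 76599235), with 12.5 ± 0.0832 and 12.5 ± 0.0199 (SD, n = 4 and 2). Why the folds at these regions were so alike was not tested, and alike folds were not read as equal signal. The leading WT-only regions were on chromosome 8 from 3754299 to 3754622 (fold 9.22 ± 3.83), on chromosome 8 from 55639681 to 55639907 (7.71 ± 1.27) and on chromosome 13 from 9834206 to 9834587 (6.91 ± 0.546; SD, n = 4 each), all outside annotated genes. The 3 leading K49A-only regions were all on chromosome 5, at 15651213 to 15651681 (fold 5.35 ± 0.338), 15498665 to 15499046 (4.11 ± 0.368) and 15490941 to 15491270 (3.29 ± 0.162; SD, n = 2 each), also outside genes.

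The sex chromosomes had a higher share of the peaks in both K49A lists than in any WT list. Chromosome X held 0.916 ± 0.411% of WT peaks (SD, n = 4) and 3.13 ± 0.584% of K49A peaks (SD, n = 2), with 6.32% of the genomic span. Chromosome Y held 0.191 ± 0.0394% and 1.95 ± 0.674% (SD, n = 4 and 2), with 3.36% of the span. In every library the percent of peaks on each of these chromosomes was below its percent of the span. Both shares of peaks separated the genotypes without overlap (exact permutation test, two-sided p = 0.133, the smallest this test can give). The cause was not tested. In absolute number, WT lists held 58 to 302 peaks on chromosome X and the K49A lists 19 and 36. Within pairs the shares on chromosome X were 0.513 and 2.71% for WT 1 and K49A 1, and beside the 3.54% of K49A 2 the share was 0.624% in WT 4 (alike in file name) and 1.17% in WT 2 (alike in title). The difference of 2.21 percentage points was 1.32 with 700 peaks per list and 3.96 at a −log10 q of at least 5.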

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

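All tests in this part were chosen after the peak lists had been seen, apart from the overlap of the weaker K49A peaks and the covered length on chromosome 5, whose outcomes were written down before they were computed. WT 1 covered 5.76 Mb with peaks, far below the other 3 WT libraries (13.5 to 14.5 Mb), by a gap that exceeds Dixon's limit for 4 values. About 1 in 20 such groups exceeds it by chance, and both ends of 12 measures were examined.

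The small number of K49A regions could have technical sources. Lower depth as the source is argued against for K49A 2, whose background pileup was 6.55, above the highest WT value of 5.58. That of K49A 1 was 4.19, under the lowest WT value of 4.26 in WT 1, at 0.983 times it. This approximate measure was solved from called peaks only and total depth is unknown, so depth is not excluded. The authors' q limit, which adapts to how much of a library is enriched, widened the gap but was not its whole cause, since at a −log10 p of at least 5 the lowest WT list was still 6.10 times the highest K49A list, against a spread of 2.00 among WT lists. A batch shared by libraries alike in file name is argued against by the smaller within-pair fold of 16.2, against 2.47 between WT libraries, and pairing by title, which disagrees for K49A 2, gives 16.2 and 20.1. What stays open includes the genotype itself and any difference in digestion, decondensation or gel recovery that went with it. Differences in sperm input, in duplicate reads and in the animals behind a library stay open too. None of these was tested.

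The lower share of K49A regions at gene ends is not what a mere cut to the strongest regions of a common ranking would give, since the lowest WT share among the 700 strongest peaks was 44.1%, against at most 12.3% in K49A. The strongest K49A regions may mark sequence that is high in every library, for example collapsed copies in the reference, because at least 96.9% of those with a −log10 p of at least 20 were called in all 4 WT libraries. Scattered false calls as the source of all the weaker ones are argued against. Of K49A peaks with a −log10 p under 10, 27.9% in K49A 1 and 18.1% in K49A 2 met such a peak of the other K49A library. Random placement gave at most 0.202%. The rest met none, and 28.9% of these weaker peaks in K49A 1 and 45.9% in K49A 2 were in no WT library. How many of them are false calls is therefore not known. A candidate explanation for the shared ones is that both K49A libraries see the same repeated or poorly mappable stretches. A lower nucleosome signal at gene ends in K49A, relative to the rest of the same library, stays open as a biological one. Calls are relative to a library's own background, so they cannot say whether nucleosomes at gene ends were lost. No mappability or sequence was used here to separate these.

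Chromosome 5 from 14 to 16 Mb held 45 and 70 K49A peaks against 30 to 49 WT peaks (exact permutation test, two-sided p = 0.267), although the K49A lists were over 10 times shorter. It also held 14 of the 21 regions called in both K49A and no WT library. Splitting of regions that WT lists hold whole could inflate such a count, and the test left this open, with a covered length of 18357 bp in K49A 1, below the highest WT value of 19822 bp, and 33543 bp in K49A 2. A difference in copy number between the mutant line and the wild-type animals was not tested.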

How the results depend on the processing

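The directions of peak number, covered length, median width and the share on chromosome X held under every alternative run, though the exact permutation test cannot pass 0.05 with 4 and 2 libraries, so its p-values say nothing about stability. Sizes did not hold, since covered length went from -5.06 to -0.69 with equal list sizes and -0.31 at a −log10 p of at least 20, and width from -0.63 to -0.03 at that level. Alternatives on a common p level and on other window widths were chosen after seeing the data. A −log10 q of at least 5 left 604 to 2084 WT and 229 and 302 K49A peaks. The log2 difference in peak number was -3.43, -2.92, -1.17 and -0.25 at a −log10 p of at least 5, 6, 10 and 20. At a −log10 p of at least 20 the K49A minus WT difference turned to 0.67 percentage points for the share at gene ends and 0.21 for gene bodies, and the cause was not tested. Overlap of K49A with WT peaks moved from 55.6% to 72.6% at a −log10 q of at least 5, 30.9% with equal list sizes, and 74.0 and 84.8% at a −log10 p of at least 10 and 20. It was 47.4 to 63.9% when 1 library was left out. The count of WT-only regions moved from 6161 to 1515 with 0.5 of the region covered, 50 at a −log10 q of at least 5, 24 with equal list sizes, and 1818, 570, 21 and 9 at a −log10 p of at least 5, 6, 10 and 20. Leaving out 1 library gave 6234 to 9485, the highest without WT 1, by requiring fewer calls. Leaving out 1 library gave -4.80 to -4.26 for peak number, -5.38 to -4.77 for covered length and -35.9 to -30.9 percentage points for gene ends. The number of gene lists with lower odds ratios in both K49A libraries was 0, and 1 with windows of 2000 bp. The difference in log2 odds ratio (K49A minus WT) changed sign for ribosomal protein genes, to 3.69 at a −log10 q of at least 5, 1.70 with equal list sizes and 0.61 with windows of 500 bp (-0.21 to 0.16 when 1 library was left out), for developmental transcription factors, to -0.18 with windows of 500 bp, and for imprinted genes, to -0.0034 with equal list sizes. With the main settings these 3 lists had 0 to 2 K49A members with a peak. The cause of the other moves was not tested. With a replicate block on the numbers 1 and 2 of the titles, peak number differed by -4.17, covered length by -4.72, width by -0.67, gene ends by -37.0, gene bodies by -28.7 and chromosome X by 2.29, and no direction changed. The labels do not say that a number marks a shared day or animal, and 2 shared numbers are too few to check it. Pairing by file name, which disagrees with the titles for K49A 2, gave -4.40 for peak number, -0.37 for width and -34.1 for gene ends. An alternative promoter window (2 kb upstream to 500 bp downstream) and the alternatives for CpG islands, GC content and repeats were not run. They need strand or sequence. The planned promoter measure, 1 kb either side of the start of transcription, was replaced by gene ends. Unknown depth limits all statements to regions above the authors' threshold.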

Other observations

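The values in this part were chosen after the data were seen. The K49A peaks were crowded into a few stretches of the genome. The 10 densest 1 Mb windows of each list held 21.3 and 25.4% of K49A peaks, against at most 4.71 and 4.33% in random placements, where the windows were chosen anew in each placement. Those of the WT lists held 1.99 to 2.30% of WT peaks, also above random placements of the same lists (means of 0.879 to 1.12%, at most 1.23%). The densest K49A window, on chromosome 5 from 15000001 to 16000000, held 35 and 52 K49A peaks and 19 to 31 WT peaks. It includes Speer4c and Speer4d, of a multicopy family named for expression in spermatogenesis. The next, on chromosome 8 from 20000001 to 21000000, held 25 and 49 K49A peaks and 40 to 57 WT peaks and includes the beta-defensin gene Defb33. The window on chromosome 4 from 147000001 to 148000000, with a cluster of zinc finger genes such as Zfp978 and Zfp991, held 12 and 36 K49A peaks and 39 to 90 WT peaks. That on chromosome 1 from 85000001 to 86000000, with Sp100, Sp110 and Sp140, held 13 and 25 against 24 to 60. The window on chromosome 11 from 3000001 to 4000000, with Sfi1, held 14 and 15 against 25 to 39.

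The 4 WT libraries differed among themselves at high stringency. WT 1 and WT 4 held 692 and 863 peaks with a −log10 p of at least 10, of which 60.3 and 56.7% lay at gene ends. WT 2 and WT 3 held 324 and 376, of which 24.4 and 30.3% did. With lists of 700 peaks, WT 1 and WT 4 overlapped in 49.4% and WT 2 and WT 3 in 48.3%, above the other WT pairs (36.9 to 40.7%). WT 2 and WT 3 also had the widest peaks (medians of 557 and 542 bp, against 404 and 366 bp) and the larger shares on chromosome X (1.17 and 1.36%, against 0.513 and 0.624%). By file name, WT 1 and WT 4 are the libraries with a K49A partner, whereas by title WT 1 and WT 2 are.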
